A study of Mus musculus with 2 samples.

How the data were processed

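RENCA is a mouse kidney cancer line that grows in BALB/c mice. Tumours grown from RENCA cells in the kidney were dissociated and droplet single-cell RNA-seq libraries were made. The series description states a sort for CD45, the surface protein of white blood cells, while the sample records name an epithelial cell type and no sort. The sort was taken as stated. There was 1 library from tumours labelled SMYD3 knockdown and 1 from tumours labelled WT. The deposited count matrix holds whole UMI counts (unique molecules) per gene and cell for both libraries, and per the file headers it was made with Cell Ranger 7.1.0. The genome build, mm10, is named in the submitters' processing notes. The annotation release is not given in the sources used here, nor is whether depth was equalised between the libraries when they were merged. A second deposited table names the library of each barcode. Barcodes were matched to it by sequence, because the barcode suffixes and the sample numbers run in opposite order: suffix 2 held the 10186 barcodes of the library labelled SMYD3 knockdown and suffix 1 the 9265 of the library labelled WT, with 22 sequences present in both.

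The matrix lists 55357 gene identifiers, of which 52081 (94.1%) were found in GENCODE vM21, the mm10 annotation used for coordinates. Gene symbols were taken from the deposited gene list. Counts were summed as deposited, so the split of reads among close copies, such as the trypsinogen genes Prss2, Try4 and Try5, the lysozyme genes, the heat shock genes Hspa1a and Hspa1b and the histone genes, is uncertain.

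Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Of the barcodes, 463 and 395 had under 200 genes, 38 and 0 had under 500 UMIs, and 620 and 582 had over 20% mitochondrial UMIs (knockdown label first). Doublets were scored with Scrublet, run through scanpy 1.11.5, in each library, and the highest scores were removed at 0.8% per 1000 cells, which took 723 cells (7.60%) and 603 cells (6.95%). The caller's own threshold marked 0 cells in either library and was therefore not usable. This left 8784 and 8079 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 28 clusters over both libraries together, without integration. Clusters were named from 15 marker lists. A name needed 3 detected markers, and a cluster stayed unnamed where its 10 leading genes went against the name, or where 3 times its median UMI count fell short of the median of its own libraries and no marker was among the leading genes. The score that assigns a cluster to a list was changed once after the data were seen, because a version based on z-scores failed for the majority class. Names end in "-like" because no annotation of the cells was used. Monocyte-macrophage-like and T-cell-like cells were clustered again for subclasses, and CD4 and CD8 T-cell-like subclusters stayed unnamed because their lists held fewer than 3 markers.

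UMIs were summed per library and class and divided by the class total to give CPM. Classes of at least 100 cells in each library were compared. Tumour-like cells, with fewer, were described because the knockdown was made in the grafted tumour cells. Whether every tumour-like cell was a grafted cell was not tested. With 1 library per group no test was possible, and no p-value or standard error was computed. Counts of genes past 1.5-fold describe these 2 libraries and are not counts of changed genes. Intervals are exact at 95% (Clopper-Pearson for shares, Poisson for sums, conditional binomial for ratios of sums, Newcombe for differences of shares) and cover counting error only, neither the spread between mice nor that between libraries. A ratio against 0 UMIs is given as a lower bound computed with 3 UMIs in the class and library at 0. Ratios use CPM without a pseudocount. Values of gene lists are medians of log2 (CPM plus 5), knockdown label minus WT label, over members with at least 20 UMIs and 10 CPM in either library. A list's percentile is its place among 10000 random lists of the same size matched on mean expression in 20 bins, and describes these 2 libraries only. Counting intervals of list medians come from 1000 Poisson resamplings of the sums.

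Genes were named by a fixed rule. Smyd3, Srebf1, Cd47 and Sirpa were named throughout. In each of the largest immune classes with at least 200 cells per library (3 classes qualified), the 10 genes with the largest and the 10 with the smallest log2 (CPM plus 5) difference were named among genes of at least 50 CPM and 30 UMIs in the higher library and at least 1.5-fold apart, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, unnamed, sex-linked and other classes' marker genes. Up to 4 members with the largest difference were named per described list. Markers, gene lists, filters, naming rules and most alternative settings were fixed before the data were examined. The list of pancreatic enzyme genes, the omission of Cela1 from it, and any gene said to be chosen after its values were seen, came later.

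The statistics were tested on simulated counts of 55357 genes with known changes in 200 of them, separately for each class. A changed gene counted as recovered where its values were at least 20% apart in the simulated direction. Among genes changed 1.5-fold, this recovered 98.5% for monocyte-macrophage-like, 95.5% for neutrophil-like, 94.0% for dendritic-cell-like, 91.0% for T-cell-like and 94.0% for tumour-like sums. The 95% intervals held the simulated fold in 95.5%, 96.5%, 96.0%, 93.5% and 96.5% of the changed genes, in the same order, and a raised list came at percentile 100 in each. The simulated sums were independent Poisson counts without spread between cells or libraries. They check the computation and not whether the intervals hold for the real data.

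Alternative settings covered the doublet treatment, the filters, the clustering resolution, clustering of each library alone, naming of single cells by marker score, thinning of every cell to 1000 UMIs, the scaling, the gene minimum, the pseudocount and the mean in place of the median. Thinning left out 635 and 540 shallower cells, 424 and 324 of them neutrophil-like. Settings added after the data were seen were list values relative to the other classes, cells of at least 10000 UMIs, shares without the shallow monocyte-macrophage-like clusters, and shares of immune cells other than neutrophil-like cells. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and statsmodels 0.14.6, and figures matplotlib 3.10.9.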

Results

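Single-cell RNA-seq was performed on cells, described as sorted for CD45, of RENCA kidney tumours from BALB/c mice, with 1 library labelled SMYD3 knockdown and 1 labelled WT. The library labelled SMYD3 knockdown held 95803321 UMIs in 10186 barcodes (median 8309.5 per barcode) and the library labelled WT 91523767 UMIs in 9265 barcodes (median 9119). After filtering, 8784 and 8079 cells remained, of which 8621 and 7935 were immune cells. No replicate exists for either label, so every difference is one between 2 libraries, and intervals cover counting error only. Because a lower level of the targeted gene was not detectable in tumour-like cells, the libraries are named by their labels throughout.

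The first comparison asked whether the knockdown was visible and how the genes named in the study's title, the methyltransferase Smyd3, the lipid-synthesis regulator Srebf1 and the anti-phagocytic surface protein Cd47, were expressed in the grafted tumour cells and around them. In tumour-like cells, a single cluster led by Cryab, Krt8 and Krt18, Smyd3 stood at 20.3 CPM (95% Poisson interval 13.6 to 29.2, 29 UMIs) in the 48 cells of the library labelled SMYD3 knockdown and at 17.0 CPM (12.1 to 23.1, 40 UMIs) in the 85 cells of the library labelled WT. Cd47 was 4.78-fold higher in the library labelled SMYD3 knockdown (ratio interval 4.18 to 5.49), at 584 against 122 CPM from 834 and 288 UMIs. Srebf1 stood at 49.0 against 42.0 CPM (ratio 1.17, 0.847 to 1.60), and Sirpa, which encodes the receptor of CD47 on myeloid cells, at 137 against 142 CPM (ratio 0.966, 0.806 to 1.16).

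The Smyd3 ratio in tumour-like cells was 1.20 with an interval of 0.716 to 1.98. A lower Smyd3 level in the library labelled SMYD3 knockdown was therefore not seen, and a reduction to a ratio between 0.716 and 1 was not detectable at this depth. Ratios under 0.716 lay outside the interval, which covers counting error only. Because the interval includes 1, the counts give no direction for Smyd3 in these cells. The median tumour-like cell had 522 CPM of Cd47 in the library labelled SMYD3 knockdown and 77.2 CPM in the library labelled WT. In monocyte-macrophage-like cells the ratios lay closer to 1: Cd47 stood at 309 against 292 CPM (ratio 1.06, 1.04 to 1.08), Sirpa at 365 against 352 CPM (1.04, 1.02 to 1.05), Smyd3 at 10.6 against 9.30 CPM (1.14, 1.03 to 1.27) and Srebf1 at 22.8 against 19.8 CPM (1.15, 1.07 to 1.24). Cd47 ratios were 0.886 (0.813 to 0.965) in neutrophil-like, 0.977 (0.918 to 1.04) in dendritic-cell-like and 1.24 (1.01 to 1.52) in T-cell-like cells. Sirpa ratios were 0.968 (0.841 to 1.12) in neutrophil-like and 1.04 (0.945 to 1.15) in dendritic-cell-like cells, and Srebf1 in dendritic-cell-like cells had a ratio of 1.37 (1.02 to 1.85). In neutrophil-like cells Smyd3 rested on 8 and 7 UMIs and Srebf1 on 12 and 7, and in T-cell-like cells Smyd3 rested on 6 and 12 UMIs, Srebf1 on 6 and 6 and Sirpa on 5 and 13, too few to tell the libraries apart. In dendritic-cell-like cells Smyd3 had 17 UMIs in each library (ratio 1.27, 0.610 to 2.65). With every cell thinned to 1000 UMIs, the Smyd3 and Srebf1 ratios of monocyte-macrophage-like cells were under 1.

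**Figure D1:**
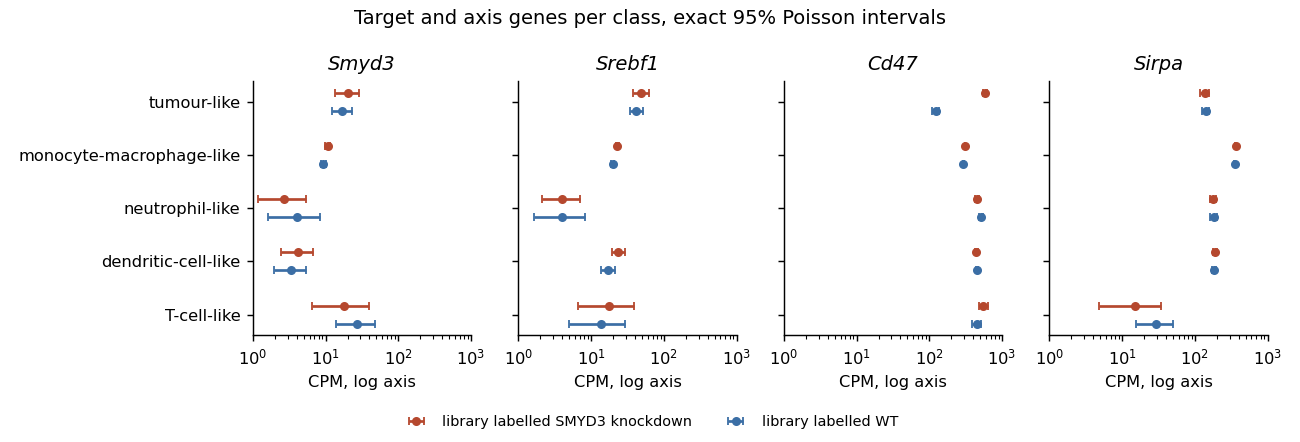
Expression of Smyd3, Srebf1, Cd47 and Sirpa in 5 cell classes, in CPM on a log axis, for the library labelled SMYD3 knockdown (red) and the library labelled WT (blue). Points are summed UMIs over the class total and bars exact 95% Poisson intervals; Cd47 in tumour-like cells lies at 584 against 122 CPM, with intervals that do not overlap.

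In GRCm38/mm10, Smyd3 (ENSMUSG00000055067) lies on chromosome 1 from 178951960 to 179518041 on the minus strand and Srebf1 (ENSMUSG00000020538) on chromosome 11 from 60199089 to 60222581 on the minus strand. Cd47 (ENSMUSG00000055447) lies on chromosome 16 from 49800533 to 49915010 and Sirpa (ENSMUSG00000037902) on chromosome 2 from 129592835 to 129632228, both on the plus strand. Coordinates are those of the whole annotated gene, and the knockdown target within Smyd3 is not given in the sources used here.

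The second comparison asked how the immune cells of each library were composed. Whether all of them came from the tumours was not tested. Neutrophil-like cells, led by S100a9, Retnlg and G0s2, made up 24.8% of immune cells in the library labelled SMYD3 knockdown (2136 of 8621, exact binomial interval 23.9 to 25.7%) and 16.6% in the library labelled WT (1320 of 7935, 15.8 to 17.5%), a difference of 8.14 percentage points (6.91 to 9.37). Monocyte-macrophage-like cells made up 69.8% (68.8 to 70.8%) and 75.6% (74.7 to 76.6%), a difference of -5.86 points (-7.21 to -4.50), from 6016 and 6002 cells. This direction depended on the neutrophil-like cells: among immune cells without them, monocyte-macrophage-like cells made up 92.8% and 90.7%, a difference of 2.03 points (1.09 to 2.98). Dendritic-cell-like cells stood at 3.92% (3.52 to 4.35%) and 5.32% (4.83 to 5.83%). The lymphoid classes were small and each had a lower share in the library labelled SMYD3 knockdown: T-cell-like cells at 1.17% against 1.66% (101 and 132 cells), NK-cell-like cells at 0.244% against 0.517% (21 and 41 cells) and B-cell-like cells at 0.104% against 0.227% (9 and 18 cells). The interval of the B-cell-like difference, -0.263 to 0.003 points, included 0. Without the neutrophil-like cells the dendritic-cell-like difference was -1.17 points (-1.97 to -0.367) and the T-cell-like one -0.438 points, with an interval (-0.895 to 0.016) that included 0.

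Of all kept cells, tumour-like cells made up 0.546% and 1.05%, fibroblast-like cells, led by Col1a1 and Col3a1, 0.114% and 0.322% (10 and 26 cells), and unnamed clusters 1.20% and 0.408%. The unnamed clusters were 2 that went opposite ways, one of 93 and 0 cells led by pancreatic genes such as Reg3b and Ctrb1 and one of 12 and 33 cells led by genes such as Cryab, Emp2 and Krt8. The latter had a median of 866 UMIs and was left out of the tumour-like share, whose direction it had. The sort for CD45, where made as described, sets the share of these non-immune cells. Neutrophil-like cells had a median of 1338 and 1262 UMIs against 11555.5 and 11176 in monocyte-macrophage-like cells, so the UMI and gene minimums can set their share.

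**Figure D2:**
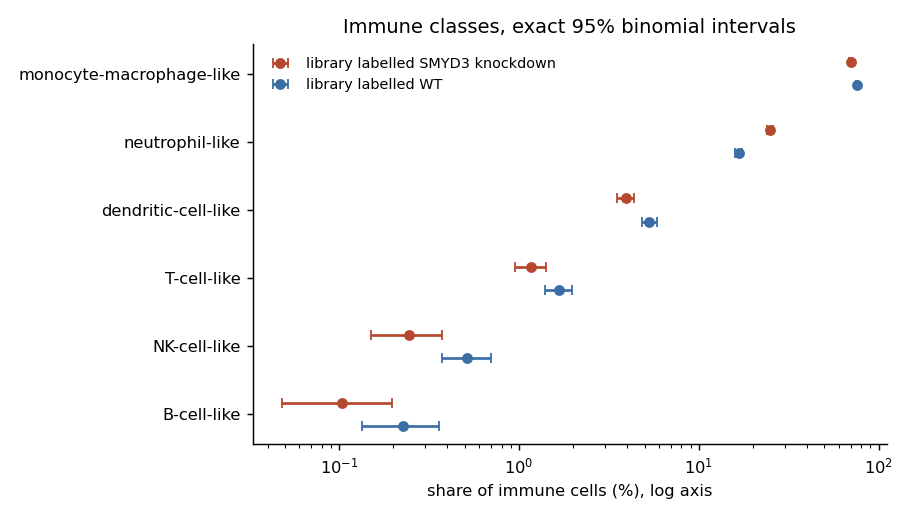
Shares of 6 immune classes among immune cells, in percent on a log axis, for the library labelled SMYD3 knockdown (red) and the library labelled WT (blue), with exact 95% binomial intervals. Neutrophil-like cells lie at 24.8% against 16.6%, and the other 5 classes are lower in the library labelled SMYD3 knockdown.

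Subclusters of monocyte-macrophage-like cells were not compared as macrophage-like and monocyte-like. One of 37 cells named macrophage-like was led by neutrophil genes such as S100a9 and Retnlg, another of 209 cells by pancreatic enzyme genes such as Clps and Ctrb1, and other subclusters had no marker of their own name among their leading genes. Within T-cell-like cells, regulatory T-cell-like cells, led by Foxp3, Ikzf4 and Ctla4, numbered 12 of 101 and 22 of 132 (11.9%, 6.29 to 19.8%, against 16.7%, 10.8 to 24.1%), and gamma-delta T-cell-like or innate lymphoid-like cells 8 and 11. The intervals of these differences included 0. Another 81 and 99 T-cell-like cells lay in unnamed subclusters, and the difference intervals of 3 of these excluded 0 while their ratio intervals included 1, so a difference in T-cell composition stays open.

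The third comparison asked how each immune class differed in expression. In monocyte-macrophage-like cells, Cebpb, a transcription factor of myeloid differentiation, stood at 265 CPM in the library labelled SMYD3 knockdown and 1055 CPM in the library labelled WT (ratio 0.251, 0.247 to 0.255). The cholesterol-pathway genes Fdps and Idi1 were 1.60-fold and 1.57-fold higher in the library labelled SMYD3 knockdown, the cholesterol 25-hydroxylase gene Ch25h 1.87-fold higher, and the chemokine gene Cxcl3 1.67-fold higher. Chil3, which encodes a chitinase-like protein of monocytes and alternatively activated macrophages, was 1.53-fold higher, and Retnla, another gene of alternative activation, lower with a ratio of 0.398 (0.368 to 0.429), from UMIs in 1.88% and 3.20% of the cells. Of 14 pancreatic digestive enzyme genes, 13 had at most 3 UMIs in all cells of the library labelled WT, while Cela1 had 1832 there. Ctrb1 had 6113 UMIs against 1 in monocyte-macrophage-like cells.

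The 10 named genes higher in the library labelled SMYD3 knockdown were Ctrb1, Prss2, Try5, Pmepa1, Ch25h, Cxcl3, Fdps, Cxcl14, Chil3 and Idi1. Prss2 had 4102 UMIs against 1 and Try5 3715 against 0 (at least 1190.4-fold higher), while Pmepa1, a regulator of TGF-beta signalling, had a ratio of 1.97 (1.86 to 2.08). The 10 lower genes were Cebpb, Ppp1r14b (ratio 0.435), Mucl1 (0.425), Ube2m (0.480), Sec61g (0.470), H2ac24 (0.469), the non-coding RNA Chaserr (0.482), Snx20 (0.505), Lyz1 (0.534) and Akirin2 (0.527). Of these 20 genes, 8 were at least 1.5-fold apart in the same direction in neutrophil-like, dendritic-cell-like and tumour-like cells alike, on the log2 (CPM plus 5) scale. Cebpb (chromosome 2, 167688915 to 167690418, plus strand) had ratios of 0.261 in neutrophil-like, 0.289 in dendritic-cell-like and 0.283 in tumour-like cells. The largest monocyte-macrophage-like cluster differed between the libraries: it was number 1, led by Cx3cr1 and Vcam1, in the library labelled SMYD3 knockdown and number 0, led by Clec10a and Ccl8, in the library labelled WT.

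Among fixed gene lists in monocyte-macrophage-like cells, the targets of SREBP, the transcription factor family of lipid synthesis, had a median log2 difference of 0.20 (counting interval 0.18 to 0.26; knockdown label minus WT label), at percentile 100 of matched random lists. Of its 16 measured members 15 were higher in the library labelled SMYD3 knockdown, 2 of them by at least 1.5-fold (Fdps and Idi1), followed by Fdft1 (ratio 1.39) and Elovl6 (1.47). The same list had a median of 0.21 (8 measured members, percentile 98.9) in neutrophil-like cells and of -0.05 (18 members, 8 of them higher, percentile 40.9) in dendritic-cell-like cells. The pro-inflammatory (M1-like) list had a median of -0.10 (-0.14 to -0.07, percentile 1.76) with 0 of 14 members 1.5-fold apart: Il6 had a ratio of 0.743, Socs3 of 0.831, Tnf of 1.21 and Ptgs2 of 0.850. This median was -0.04 with each cell weighing the same and 0.00 when every cell was thinned to 1000 UMIs. The alternative (M2-like) list had a median of -0.01 (-0.05 to 0.01, percentile 34.3) over 17 members that went both ways, with Chil3 and Arg1 (ratio 1.45) higher and Retnla and Lyve1 (0.757) lower. Lyve1 is among the leading genes of cluster 0, the largest of the class in the library labelled WT. Class values of such genes therefore do not separate expression from the mix of clusters. The same limit holds for Chil3 (clusters 4 and 12) and for the interferon genes Rsad2, Ifit2 and Mx1 (cluster 15). In neutrophil-like cells it holds for Retnlg (cluster 5).

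Phagocytosis and engulfment receptors, a list that also holds ligands and adaptors such as Gas6 and Elmo1, had a median of 0.05 (0.04 to 0.06, percentile 90.0), with 0 of 22 members 1.5-fold apart. Cd36 had a ratio of 0.763, Axl of 1.21, Fcgr1 of 1.16 and Cd14 of 0.872. Lipid-associated macrophage genes had 0 of 15 members 1.5-fold apart, with Cd9 (1.38) and Spp1 (1.33) higher and Gpnmb (0.692) and Cd36 lower. MHC class II genes had a median of -0.04 (-0.05 to -0.03, percentile 19.2) and interferon response genes one of -0.03 (-0.08 to 0.00, percentile 35.0), again with 0 members 1.5-fold apart, and the sign of both turned with the setting (0.09 for MHC class II with each cell weighing the same, 0.04 for interferon members of at least 100 UMIs and 50 CPM). The MHC class II members farthest apart were H2-DMb2 (1.25-fold lower), H2-DMa (ratio 1.19), Ifi30 (1.12) and H2-Aa (0.906), and those of the interferon list Rsad2 (0.758), Ifit2 (0.748), Bst2 (1.23) and Mx1 (0.750). The dissociation and heat stress list, a measure of sample handling, had a median of -0.21 (percentile 0.00) in these cells and of 0.22 (percentile 100) in neutrophil-like cells.

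In neutrophil-like cells the 10 named genes higher in the library labelled SMYD3 knockdown were without exception genes of pancreatic secretion: Ctrb1, Prss2, Try5, Try4, Pnlip, Cela3b, Cpa1, Clps, Cpb1 and Sycn. Ctrb1, the chymotrypsinogen gene on chromosome 8 (111686519 to 111691010, minus strand), had 1665 UMIs against 0 (at least 324.2-fold higher), Pnlip, which encodes pancreatic lipase, 652 against 0, and Sycn 367 against 0 (at least 71.5-fold higher). The lower genes were Cebpb (1102 against 4227 CPM), Jdp2 (ratio 0.364), Snx20 (0.424), Ppp1r14b (0.395), Sec61g (0.414), Basp1 (0.466), Cdc34 (0.422), the chemokine gene Ccl8 (0.478), the acute-phase gene Saa3 (0.528) and Alyref (0.520). Of the 20 genes, 13 were apart in the same direction in the other 3 classes. The macrophage transcripts Apoe (ratio 0.711) and C1qa (0.749) were also lower in neutrophil-like cells of the library labelled SMYD3 knockdown. In the library labelled WT, Ccl8 had 1.61 UMIs per neutrophil-like, 1.60 per T-cell-like and 2.12 per dendritic-cell-like cell. Monocyte-macrophage-like cells there had 22.3 each. The Ccl8 ratios of the other immune classes therefore do not separate expression from RNA of macrophages. Cluster 5, led by Retnlg, was the largest neutrophil-like cluster in the library labelled SMYD3 knockdown. In the library labelled WT it was cluster 6, led by Ciart and Gadd45b.

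Scaling by the median ratio of genes moved all log2 values of neutrophil-like cells by 0.11, since the median gene lay at -0.11 there, so list medians between -0.11 and 0 are higher than that gene and turn positive with that scaling. Without it, the tumour neutrophil and suppressor list had a median of 0.03 (-0.02 to 0.10, percentile 78.8), with 1 of 20 members 1.5-fold higher, Arg1 (ratio 1.65, 1.37 to 2.01). Its other members farthest apart were Clec4e (0.708), Wfdc17 (0.712) and the chemokine receptor gene Cxcr4 (1.40). Maturation and granule genes had a median of 0.00 (-0.06 to 0.11, percentile 67.6), with Ly6g at 31.5 against 16.1 CPM (ratio 1.96, 1.27 to 3.11), Retnlg (1.49) and Ltf (1.48) higher and Mmp9 (0.788) lower. Interferon response genes had a median of -0.10 (-0.16 to 0.13, percentile 47.5), with 2 of 23 members 1.5-fold lower, Ifit3 (0.349) and Cxcl10 (0.595), and Irf7 (1.46) and Rsad2 (0.746) next. Chemokine genes had a median of -0.01 (percentile 53.9), with Ccl8, Cxcl10, Ccl9 (0.706) and Cxcl1 (0.783) farthest apart, and hypoxia and glycolysis genes one of -0.05 (percentile 39.5), with Adm (0.266, from 15 and 33 UMIs), Gapdh (1.32), Bnip3 (0.840) and Egln3 (0.847). The mitochondrial genome list, which also follows cell and RNA quality, had a median of -0.48 (-0.55 to -0.42, percentile 0.00) with 0 of 10 members higher, and MHC class II genes one of -0.28 (-0.41 to -0.19, percentile 2.09) with 3 of 8 members at least 1.5-fold lower. Without doublet removal the MHC class II median was -0.07. The macrophage transcripts Apoe (ratio 0.711) and C1qa (0.749) were lower in the same cells. The MHC class II median therefore does not separate expression from RNA of macrophages. The stress list, with Fosb (1.49), Jun (1.36), Hspa1a (1.33) and Hsp90aa1 (1.29), had 0 of 19 members 1.5-fold apart.

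Dendritic-cell-like cells of the library labelled SMYD3 knockdown were higher in hypoxia and glycolysis genes. The list had a median of 0.49 (0.41 to 0.55, percentile 100), with 17 of 18 members higher in the library labelled SMYD3 knockdown and 6 of them by at least 1.5-fold. Examples were the lipid-droplet gene Hilpda (ratio 2.19, 1.88 to 2.55), Vegfa, which encodes an angiogenic factor (2.51, 1.62 to 3.93, from 65 and 33 UMIs), the cytokine gene Mif (1.85, 1.71 to 1.99) and Egln3, an oxygen-sensing hydroxylase gene (1.88, 1.39 to 2.57). Spp1, which encodes osteopontin, stood at 1247 against 462 CPM (2.70, 2.57 to 2.84), while the macrophage transcript Apoe stood at 334 against 598 CPM. Other myeloid genes went both ways: the M2-like list had a median of -0.05 (percentile 39.7) with 3 of 14 members at least 1.5-fold higher, Arg1 (2.23), Chil3 (2.35) and Vegfa, and the tumour neutrophil and suppressor list one of -0.02 (percentile 54.6) with 4 of 18 higher, Cxcl3 and Clec4d (1.78) among them. The stress list had a median of -0.09 (percentile 2.63), with Dnajb1 (0.580) lower. The median of the hypoxia and glycolysis list was -0.05 in neutrophil-like and 0.11 in monocyte-macrophage-like cells; the differences between classes were not tested.

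The named genes higher in dendritic-cell-like cells of the library labelled SMYD3 knockdown were Ctrb1 (294 UMIs against 0, at least 124.6-fold higher), Spp1, Upp1 (ratio 2.47), Hilpda, Mfge8 (2.01), Mif, Ass1 (1.67), Rgs1 (1.54), Plet1 (1.54) and Capg (1.53). The lower genes were Cebpb, Lyz1 (0.283), Ppp1r14b (0.361), Ccl8 (0.466), Sec61g (0.485), Ube2m (0.504), Mucl1 (0.520), Snx20 (0.505), Akirin2 (0.492) and Chaserr (0.501). For Ccl8 the limit given for neutrophil-like cells holds here too. MHC class I genes had a median of 0.16 (0.06 to 0.18, percentile 99.8), with the immunoproteasome genes Psmb8 (1.30) and Psmb9 (1.17) and Erap1 (1.25) higher and Nlrc5 (0.711) lower, although 0 of 15 members were 1.5-fold apart and the median was 0.01 relative to the other classes. MHC class II genes had a median of 0.04 (0.01 to 0.10, percentile 77.9), with H2-Oa (0.767), H2-Ab1 (1.20), Lgmn (0.839) and H2-DMa (1.15). Checkpoint and costimulatory ligands had a median of -0.13 (-0.22 to -0.03, percentile 8.39), with Pvr (0.532, 0.400 to 0.701), Nectin2 (0.604), Cd40 (0.806) and Pdcd1lg2 (0.852), and one of 0.02 relative to the other classes. Interferon response genes had a median of -0.10 (-0.17 to 0.00, percentile 12.1), with Ifit1 (0.460), Ifit2 (1.35), Cxcl10 (0.801) and Mx1 (0.798), and chemokine genes one of -0.03 (percentile 32.2), with Cxcl3 (2.78), Ccl8, Cxcl1 (0.708) and Ccl12 (0.765).

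T-cell-like cells, 101 and 132 in number, were higher in cytotoxic effector genes in the library labelled SMYD3 knockdown, with a list median of 0.63 (0.41 to 0.77, percentile 100) and 9 of 15 members at least 1.5-fold higher. The chemokine gene Xcl1 had a ratio of 5.61 (3.50 to 9.38) and the granule gene Nkg7 of 1.96 (1.66 to 2.33), whereas Gzma, a granzyme gene, had a ratio of 0.251 (0.180 to 0.343) and Ifng, the interferon gamma gene, of 0.438 (0.286 to 0.655). Cd8a stood at 423 against 247 CPM (1.71, 1.33 to 2.22) and Foxp3 at 56.5 against 85.2 CPM (0.664, 0.361 to 1.18). Cd8a UMIs were present in 44.6% and 25.8% of the cells (knockdown label first). The cytotoxic list value therefore does not separate expression from the mix of T-cell subsets. The list also holds the chemokine genes Ccl3 (ratio 1.696) and Ccl4 (1.363), which neutrophil-like cells held too. Whether RNA of other classes added to these members was not tested. Proliferation genes had a median of -0.48 (-0.85 to -0.37, percentile 0.00), with 9 of 19 members at least 1.5-fold lower, among them Ccnb2 (0.237, from 5 and 28 UMIs), Cenpf (3.44-fold lower, from 7 and 32 UMIs), Ube2c (0.303) and Ccna2 (0.398). With each cell weighing the same this median was -0.15. Cycling T-cell-like cells formed a subcluster of 12 cells with a median of 8136.5 UMIs, so few cells of high depth weigh heavily in the sums of these genes.

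Naive and memory genes had a median of -0.33 (-0.57 to -0.03, percentile 1.26; -0.18 without doublet removal), with S1pr1 (0.531), Satb1 (0.692) and Klf2 (1.32). Regulatory T cell genes had one of -0.24 (-0.61 to 0.04, percentile 7.09), with Ctla4 (0.570), Tnfrsf9 (0.563), Izumo1r (0.563) and Ikzf2 (0.671). Exhaustion and inhibitory receptor genes had a median of -0.08 (-0.38 to 0.30, percentile 46.7), with Pdcd1 (1.99) and Cd160 (1.88) higher, Rgs16 (0.523) lower and Havcr2 at 1 against 20 UMIs (0.066, 0.002 to 0.415). Activation genes had a median of -0.04 (-0.33 to 0.15, percentile 54.1), with Cd40lg at 2 against 21 UMIs (0.126, 0.014 to 0.517), Icos (0.684) and Cd69 (1.30). Genes of macrophages were apart in the same cells. C1qa had a ratio of 1.44 in the sums. The median T-cell-like cell went the other way, at 254 CPM (knockdown label) against 418 CPM (WT label). Apoe stood at 1601 against 1069 CPM in the sums and at 693 against 1063 CPM in the median cell. Few cells therefore weigh heavily in the sums of these genes. The phagocytosis list had a median of 0.82 and the M2-like list of 1.10, MHC class II genes had one of -1.47 with H2-Aa at 7 against 140 UMIs, and C1qc had a ratio of 2.40. The stress list had one of 0.22 (percentile 99.7), with Egr1 (2.26) and Fosb (2.19) higher and Hspa1b (0.517) lower, and the interferon list one of 0.23 (percentile 99.3), with 6 of 14 members at least 1.5-fold higher.

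In tumour-like cells the SREBP targets had a median of 0.27 (0.14 to 0.40, percentile 100), with 14 of 19 members higher in the library labelled SMYD3 knockdown and 4 of them by at least 1.5-fold: Hmgcs1 (ratio 1.79, 1.42 to 2.25), Idi1 (1.66), Mvd (1.65) and Fdps (1.54), all of the cholesterol pathway. Proliferation genes had a median of 0.28 (0.19 to 0.40, percentile 100), with Ube2c (3.88, 3.08 to 4.92), Ccnb1 (3.80), Top2a (1.65) and Birc5 (1.57). Interferon response genes had a median of -0.47 (-0.66 to -0.32, percentile 0.00), with 11 of 26 members at least 1.5-fold lower, among them Ifit3 (0.107, from 4 and 62 UMIs), Rsad2 (0.278), Iigp1 (0.214) and Ifi44 (0.361). Chemokine genes had a median of -0.77 (-0.95 to -0.48, percentile 0.00), with Cxcl2 (0.297), Ccl6 (0.471), Ccl3 (0.413) and Cxcl1 (0.498), while Ccl8 was higher in the sums (1.80, 1.55 to 2.08). The median tumour-like cell went the other way for Ccl8, at 62.2 CPM in the library labelled SMYD3 knockdown and 103 CPM in the library labelled WT. The immune transcripts Apoe (ratio 0.582) and S100a8 (0.201) were lower in the same cells.

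MHC class I genes had a median of -0.12 (-0.15 to 0.02, percentile 4.91), with B2m (1.25) higher and Psmb10 (0.786), Tapbp (0.816) and Erap1 (0.840) lower. Hypoxia genes had one of 0.03 (-0.12 to 0.10, percentile 53.3), with Hilpda (0.483), Hk2 (0.587), Bnip3 (0.636) and Adm (0.671) lower. The stress list had a median of -0.36 (percentile 0.00) here. These values rest on 48 and 85 cells of 1 cluster. With each cell weighing the same, the interferon median was -0.20, the proliferation median 0.13 and the SREBP median 0.47. The interferon median was -0.25 without doublet removal and the chemokine median -0.42 at 10% mitochondrial UMIs. The interferon and proliferation medians changed sign when every cell was thinned to 1000 UMIs, which left 2 and 4 measured members.

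**Figure D3:**
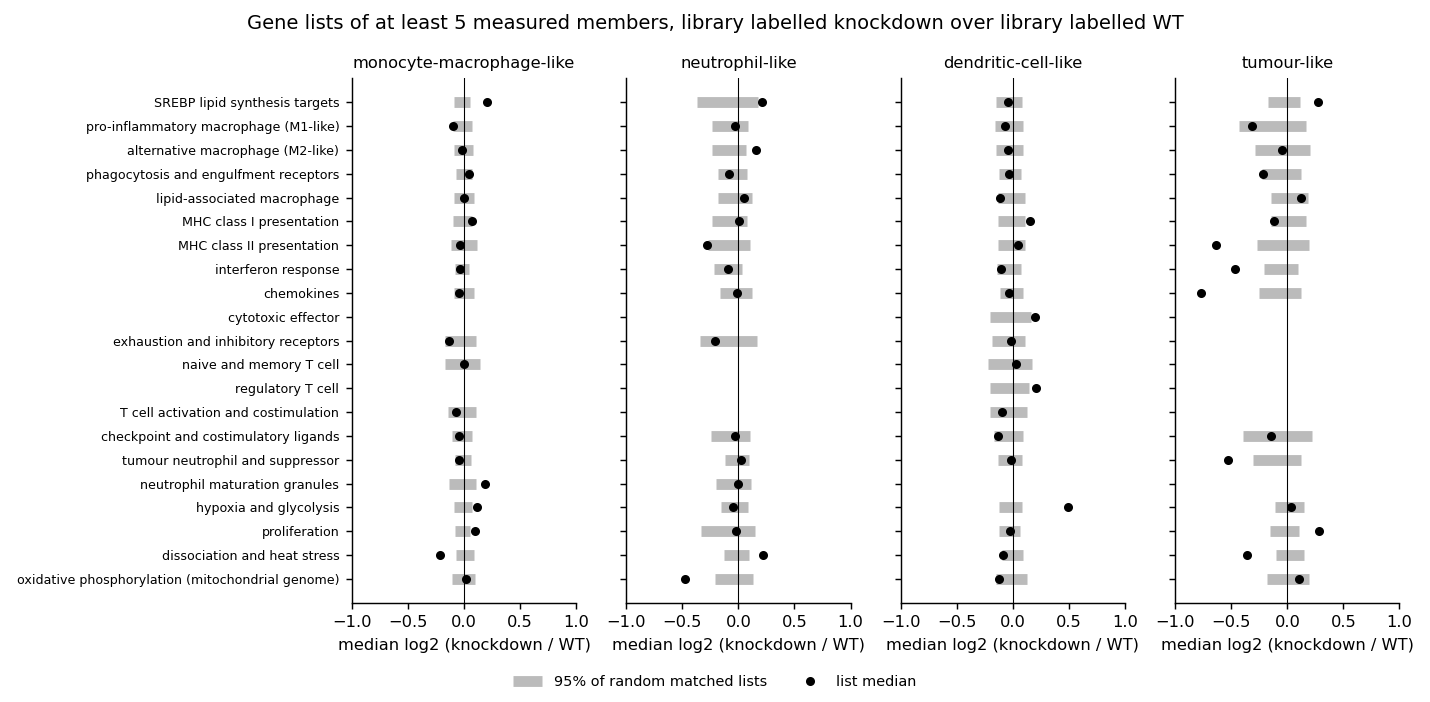
Median log2 difference (library labelled SMYD3 knockdown over library labelled WT) of gene lists with at least 5 measured members in 4 cell classes. Black points are list medians and grey bars hold 95% of 10000 random lists of the same size and expression; hypoxia and glycolysis genes in dendritic-cell-like cells lie at 0.49 and SREBP targets at 0.20 in monocyte-macrophage-like, 0.27 in tumour-like and -0.05 in dendritic-cell-like cells.

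The pancreatic enzyme genes among the named genes were summed over 13 of 14 such genes in every class. Cela1 was left out after its values were seen, because monocyte-macrophage-like and tumour-like cells of the library labelled WT also held it (1567 and 218 UMIs), so the low sums of that library follow in part from this choice. Monocyte-macrophage-like cells of the library labelled SMYD3 knockdown had a mean of 4.74 enzyme UMIs per cell (4.69 to 4.80), neutrophil-like cells 3.86 (3.78 to 3.95), dendritic-cell-like cells 4.00 (3.79 to 4.22), T-cell-like cells 3.81 (3.44 to 4.21) and tumour-like cells 7.25 (6.51 to 8.05), with a median of 3 in each of these classes. In the library labelled WT the same classes together held 3, 1, 2, 0 and 0 enzyme UMIs in that order. Ctrb1 gave between 20.2% and 22.1% of the enzyme UMIs in each of the 5 classes of the library labelled SMYD3 knockdown.

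**Figure D4:**
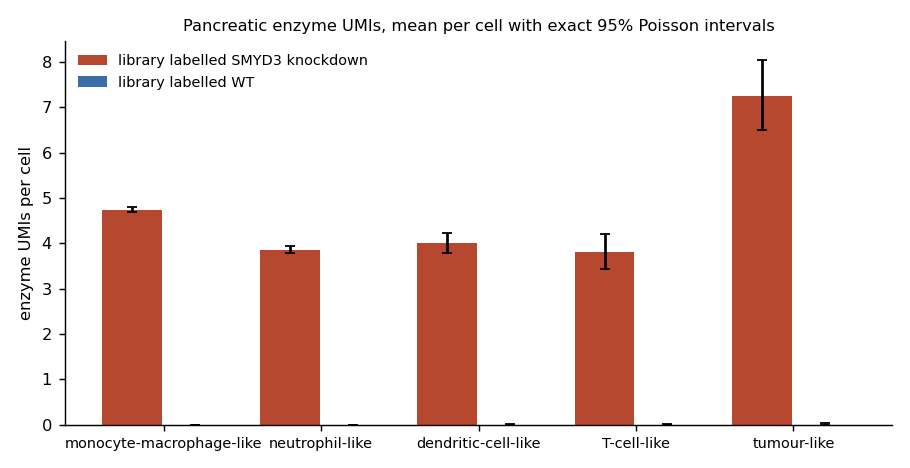
Mean number of pancreatic enzyme UMIs (13 genes, without Cela1) per cell in 5 classes, for the library labelled SMYD3 knockdown (red) and the library labelled WT (blue, at or near 0), with exact 95% Poisson intervals. Means lie between 3.81 and 7.25 UMIs per cell in the library labelled SMYD3 knockdown.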

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

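The tests of a technical difference between the libraries, of free RNA and doublets, and all tests on Cd47 were chosen after the results were seen, and those of GC content or transcript length and of macrophage RNA in the lower genes before. Cd47 drew attention because its direction differed between cell classes: log2 of the library labelled SMYD3 knockdown over the library labelled WT was 2.26 in tumour-like cells and -0.17 in neutrophil-like cells. The difference between the classes was not tested. The pancreatic RNA drew attention as a signal outside the planned comparisons: an unnamed cluster led by Reg3b, Ctrb1 and Reg2 held 93 cells in the library labelled SMYD3 knockdown and 0 in the library labelled WT, and monocyte-macrophage-like cells of the first library held 4.74 enzyme UMIs each.

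Of 28 genes at least 1.5-fold lower in monocyte-macrophage-like cells of the library labelled SMYD3 knockdown, Cebpb among them, 16 (57.1%) were also at least 1.5-fold lower in tumour-like cells, against 5.53% of all genes at 50 CPM. After the median of genes of like GC content and length was subtracted, the median log2 of the 28 genes was -0.86 (-0.80 before). The 28 genes were picked for being lower out of 3308, so the median of like genes could hardly reach their level. The test therefore cannot decide on GC content or length, and the genes were shorter (median length 1457.5 against 3008.5). Macrophage RNA at the level set by Apoe gave 3.48% of the level of these genes in tumour-like cells of the library labelled WT. This argues against RNA from macrophages in the droplets for tumour-like cells only. The other classes were not tested. Neutrophil-like cells of that library held 1963 CPM of Apoe, against 350 CPM in tumour-like cells. The share of 57.1% largely restates that the genes were lower in several classes, and with 1 library per label a technical difference between the 2 libraries cannot be told apart from an effect of the knockdown, which stays open as untested.

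Pancreatic enzyme UMIs per cell differed 1.90-fold between the highest and the lowest of 5 classes of the library labelled SMYD3 knockdown, while the median depth of the classes differed 17.6-fold. At least 1 enzyme UMI was present in 91.9% of its immune cells, which argues against doublets with pancreatic cells as the whole source. That test and the list of 13 of 14 genes, without Cela1 (1832 UMIs in the library labelled WT), replaced an earlier form after its result was seen: the 5% of cells with the most enzyme UMIs held 30.5% of them, which decided nothing, so doublets may add a part. Free RNA in the suspension is a candidate source, and the 93 cells of the unnamed cluster are a candidate for where it came from, which would place pancreatic tissue in the sample. Immune cells of such tissue could then be among the immune classes, in their shares and in their sums, which was not tested. No biological explanation was tested.

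Cd47 in tumour-like cells of the library labelled SMYD3 knockdown was not explained by RNA from immune cells, which at the level set by Apoe gave 1.10% of it, nor by a few cells or shallow cells, since among cells of at least 10000 UMIs (43 and 61) the ratio of medians was 6.10 and 0 cells of the library labelled WT lay above the other median. Swapped library labels cannot be told apart from the labels as given: the Smyd3 ratio was 1.20 with an interval of 0.716 to 1.98, which also holds values under 1. The barcode suffixes run opposite to the sample numbers, a fact that decides nothing by itself. An effect of the knockdown, a difference between tumours and one between libraries all stay open, and the direction of every difference rests on the labels.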

How the results depend on the processing

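List values relative to the other classes, cells of at least 10000 UMIs, shares without shallow clusters and shares without neutrophil-like cells were settings added after the results were seen. No paired analysis was possible because there was 1 library per label, and intervals cover counting error only. A result counted as kept where it stayed within the counting interval: 61 of 65 values of class shares, 10 of 18 of subclass shares, 48 of 55 of target genes and 419 of 518 of list medians. The number of named genes at least 1.5-fold apart in a class stayed within 1.5 times in 24 of 24 cases. With a pseudocount of 1, 20, 18 and 19 of 20 named genes were shared in monocyte-macrophage-like, neutrophil-like and dendritic-cell-like cells. Except where fewer UMIs are named, the cause of each difference was not tested.

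With each library clustered on its own, the neutrophil-like difference was 9.46 points. Without neutrophil-like cells in the denominator, the monocyte-macrophage-like difference reversed to 2.03 points. Shares of macrophage-like and monocyte-like subclusters, which were not compared because of their leading genes, also depended on the setting. The macrophage-like difference was -2.69 points, -5.63 points at 10% mitochondrial UMIs and -7.25 at resolution 2. The monocyte-like difference was -0.712 points, 2.58 without doublet removal and with Scrublet's own threshold (which called 0 cells, so the settings coincide), 5.63 at 10% mitochondrial UMIs, 3.46 at 500 genes and 1000 UMIs, 2.74 at resolution 0.5 and 6.94 at resolution 2. Without doublet removal, by either setting, the cytotoxic list of T-cell-like cells was 0.80 and the interferon list of tumour-like cells -0.25.

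With every cell thinned to 1000 UMIs, log2 of Cd47 in tumour-like cells was 2.68 (22 and 6 UMIs), and in monocyte-macrophage-like cells Smyd3 (-0.39; 45 and 59 UMIs) and Srebf1 (-0.13; 111 and 121 UMIs) reversed and phagocytosis receptors stood at 0.020. In tumour-like cells the interferon list (0.39 over 2 genes) and the proliferation list (-0.24 over 4 genes) reversed, with few UMIs left. With median-ratio scaling, Cd47 in monocyte-macrophage-like cells was 0.11, phagocytosis receptors 0.077 and the tumour neutrophil list 0.14. With each cell weighing the same, phagocytosis receptors were 0.034, the hypoxia list of dendritic-cell-like cells 0.56 and the interferon list of tumour-like cells -0.20. Phagocytosis receptors were 0.020 as a mean over members and 0.085 relative to the other classes.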

Other observations

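Hypoxia and glycolysis genes of monocyte-macrophage-like cells had a median log2 difference of 0.11 (0.07 to 0.14, percentile 99.9), with Mif (ratio 1.34), Gapdh (1.32) and Pkm (1.21) higher and Hk2 (0.766) lower in the library labelled SMYD3 knockdown. Proliferation genes of the same cells had a median of 0.10 (0.08 to 0.13). In tumour-like cells, some genes chosen after their values were seen were present in 1 library alone: Sult1d1 had 115 UMIs in the library labelled SMYD3 knockdown and 0 in the library labelled WT, in 20.8% of the cells, while Defb1 had 0 and 231 UMIs and Epcam 0 and 32, each in 2.35% of the cells of the library labelled WT.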
